A study of Drosophila melanogaster with 4 samples.

How the data were processed

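Su(var)3-7 is a zinc-finger protein of *Drosophila* heterochromatin, named as a suppressor of position-effect variegation. It was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) with the antibody Q3448 in wild-type Oregon-R embryos of *Drosophila melanogaster* aged 14 to 16 h, fixed in 1.8% formaldehyde per the labels. The series has 2 ChIP libraries and 2 input libraries (genomic DNA sequenced without immunoprecipitation). Per the labels, each input served as the control of the ChIP library with the same replicate number. The inputs have no values of their own in the tables used here. Replicate numbers come from the labels, which do not say whether the replicates are separate embryo collections.

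For each ChIP replicate the authors deposited a list of regions of significant enrichment, and for the pair a further combined list. Each region has a start, an end and a score. The deposited score is 1 number per region, and its scale and log base are not given in the sources used here. It was therefore used only to describe and rank regions within a list, apart from rank correlations of overlapping regions and, for the alternative settings, score differences averaged over the replicates. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are those of FlyBase release 5, per the file headers, which also give the sequence lengths. The region caller, its thresholds, the handling of reads that match repeats and the way the combined list was made are not given in the sources used here. How reads from repeats were placed could raise or lower the number of regions in pericentric and unplaced sequence, and a fixed calling limit would leave weaker binding out of each list. The lists hold no read counts, so the depth of each library is unknown and no interval for a level of binding could be given.

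Coverage is the percent of bases that lie inside enriched regions. Release 5 was divided into the euchromatic arms 2L, 2R, 3L, 3R and X, chromosome 4, the 6 assembled pericentric sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, called Het sequences here) and the unplaced sequence U, together 139.7 Mb. A further unplaced set, Uextra (29.0 Mb), holds 0 regions in the 3 lists and was left out of the lengths. Parts of 4 regions that run past the stated end of their sequence were removed, and 1 region that replicate 1 lists as depleted was kept apart from the enriched ones. Means are given with the standard deviation (SD) over the 2 ChIP replicates. With 2 replicates no test across samples was made: p-values measure placement along the genome within a list, not the spread between samples. Shares of regions carry 95% Wilson intervals, which cover counting error only and treat regions as independent, although neighbouring regions are not.

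Replicate overlap was the share of regions with at least 1 bp in a region of the other replicate, with the Jaccard index of covered bases (bases shared divided by bases in either list). Both were set against 1000 circular shifts of a list within each arm (one-sided permutation test, smallest possible p 0.000999). Arm enrichment was the percent of covered bases on an arm divided by its percent of sequence length, set against 1000 random placements of the regions over the sequence (two-sided permutation test, smallest possible unadjusted p 0.001998, Benjamini-Hochberg adjustment over 13 sequences). Coverage of the centromere-proximal 1 Mb of the 5 euchromatic arms was compared with the rest of the arm by 1000 circular shifts (one-sided permutation test, adjusted over 5 arms). The proximal end is the high-coordinate end of 2L, 3L and X and the low-coordinate end of 2R and 3R. Median scores were compared by 100000 permutations of the class label over regions (two-sided, smallest possible p 1e-05). A comparison counted as passed at p below 0.05 in both replicates, and the combined list was described beside them because it is not independent of them.

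These comparisons, their tests, the alternatives described as planned and the rule for named regions were set before the data were examined. Named regions are combined-list regions that overlap a region in both replicates: the 10 with the highest score on any sequence, the 10 with the highest score on the euchromatic arms outside their proximal 1 Mb, and the 5 widest. The planned test of promoters, exons, introns and intergenic sequence and the planned test of gene lists need gene positions of release 5. The gene table at hand is of release 6, so neither was run, and regions are named by position. The alternatives planned at that point were other overlap criteria, the higher-scoring 50% of each list, other windows, other sets of arms, counts of regions in place of bases, means in place of medians, merged neighbours and each replicate alone. Reassignment of 200 kb blocks in place of single regions, the addition of Uextra, the omission of the 1 replicate region that runs past a sequence end, Het sequences alone against the euchromatic arms, and the belt 1 to 5 Mb from the proximal end were added after the data were seen. The other 3 regions past an end are in the combined list, which that omission did not use.

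The tests were checked on simulated regions. With 50% of 6098 regions planted as shared, the overlap test called 10 of 10 simulations, and 0 of 10 with none planted. Chromosome 4 planted at 2-fold density was called in 8 of 10 simulations and 3LHet at 4-fold density in 10 of 10, while 7.27% of the tests on the other arms were called. The planted densities lower the true share of those other arms, so the 7.27% is not a rate of false calls. A proximal 1 Mb planted at 50% coverage was called in 20 of 20 simulations, against 0 of 20 without it. The belt test called 20 of 20 simulations with a planted belt and 2 of 20 without. A score difference of 0.2, planted in a group the size of chromosome 4 (119 regions), was recovered as 0.199 and called in 100 of 100 simulations, against 5 of 100 with no difference. Apart from the planted patterns, simulated regions were spread at random, whereas real regions lie in clusters. The simulations therefore do not give the rate of false calls for clustered regions. The planted score difference exceeded those found on chromosome 4 (0.0599 and 0.0206), and the planted proximal coverage exceeded that of X (16.1%). How often effects of those smaller sizes would be called was not simulated. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.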

Results

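The data describe where Su(var)3-7 is enriched over the genome of late *Drosophila* embryos. They consist of region lists from 2 ChIP libraries, each with its own input per the labels, and of a combined list. Replicate 1 had 6098 enriched regions over 21.28 Mb, or 15.2% of the sequence, and replicate 2 had 6295 regions over 19.77 Mb, or 14.2%. The mean was 6196.5 ± 139.3 regions and 14.7% ± 0.761 of the sequence (SD, n = 2). Median widths were 2125 bp and 2103 bp, and the widest regions measured 76800 bp and 39945 bp. The combined list had 10603 regions with a median width of 1981 bp over 33.52 Mb, 24.0% of the sequence. Read depth is unknown, since the lists give no read counts.

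The first question was on which parts of the genome the protein is enriched. Su(var)3-7 regions were densest in pericentric sequence. The Het sequences were covered over 49.2% ± 8.81 of their length, against 11.7% ± 0.198 of the 5 euchromatic arms (SD, n = 2). Coverage was highest on 3LHet at 62.4% ± 8.65, followed by 2RHet at 51.4% ± 7.53, 2LHet at 42.0% ± 6.69 and 3RHet at 41.5% ± 12.0. Chromosome 4, a small chromosome known for interspersed heterochromatin, was covered over 28.8% ± 2.84 of its length.

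Relative to length, 3LHet held 4.24-fold ± 0.369 its share of covered bases (SD, n = 2). The ratio was 3.49-fold ± 0.332 on 2RHet, 2.85-fold ± 0.308 on 2LHet, 2.80-fold ± 0.671 on 3RHet and 1.96-fold ± 0.0917 on chromosome 4. All 5 sequences exceeded the random placements in both replicates (permutation test, adjusted p 0.002597 in replicate 1 and 0.002886 in replicate 2 for each, as low as 1000 placements allowed here). Arm 2R was higher than its length predicts, at 1.29-fold ± 0.0816, with the same adjusted p. Lower ratios were found on 2L at 0.737 ± 0.0317, 3R at 0.566 ± 0.0612 and X at 0.543 ± 0.0654 in both replicates, again at those adjusted p-values. The ratio is a share of all covered bases, so dense Het sequences lower it on the other arms. The 5 euchromatic arms together were covered over 11.7% ± 0.198, against 14.7% ± 0.761 of all sequence. Arm 2L, at 10.8% ± 0.0960, lay close to these arms together and 3L, at 13.6% ± 0.169, above them. Counted by regions in place of bases, the ratios were lower on 3LHet (2.46) and 2RHet (2.12), close to those of 3RHet (2.40) and 2LHet (2.17), and all 4 still passed. XHet had a ratio of 1.92 ± 0.292 but only 23 and 18 regions, and it did not pass (permutation test, adjusted p 0.06277 and 0.2031). YHet, the assembled part of the Y chromosome, had 10 and 7 regions, a ratio of 0.503 ± 0.179 and adjusted p-values of 0.3157 and 0.02597 (permutation test). Arm 3L lay near its share at 0.929 ± 0.0367 and passed in replicate 1 alone (adjusted p 0.01417 and 0.2576). Unplaced U passed in replicate 1 alone too, with ratios of 1.28 and 0.935 (adjusted p 0.002597 and 0.2777). When 200 kb blocks in place of single regions were reassigned to arms, a setting added after the data were seen, the calls on chromosome 4 (adjusted p 0.101 and 0.1331), 2LHet (0.101 and 0.1934) and 2R (0.08905 and 0.005195) no longer passed in both replicates. With Uextra added to the length, also after the data were seen, the ratio of 3L turned from below to above 1 (1.12) and 2L no longer passed (0.890).

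**Figure D1:**
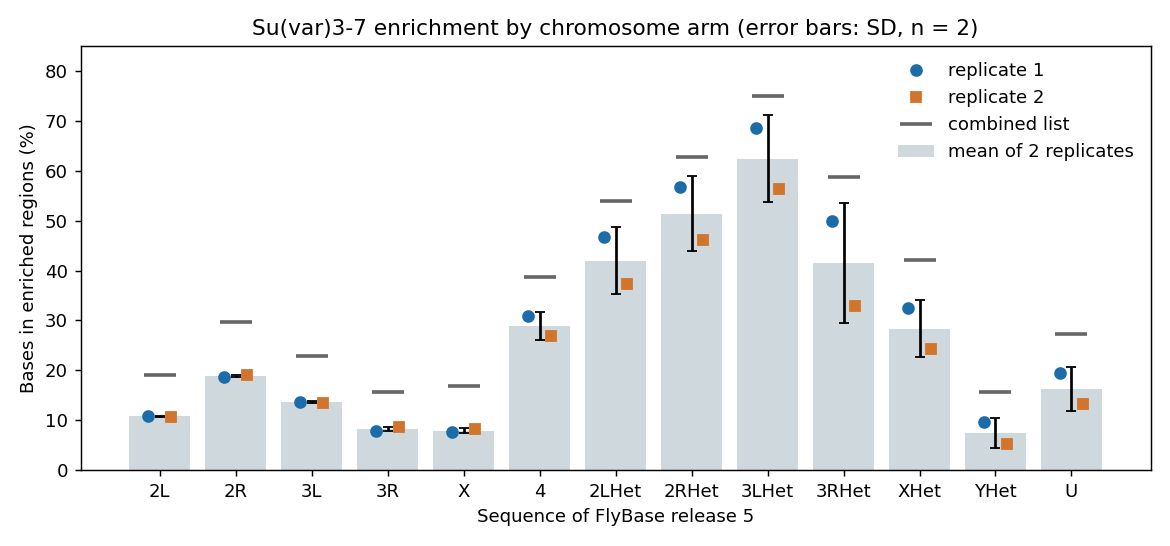
Percent of bases in enriched regions (vertical axis) on each release 5 sequence (horizontal axis); bars are means of the 2 ChIP replicates with SD, points are the replicates and grey dashes the combined list. 3LHet is highest at 62.4% and X and YHet are lowest at 7.96% and 7.47%; replicate 1 lies above replicate 2 on all 6 Het sequences.

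The second question was how enrichment is distributed along the euchromatic arms. Regions were concentrated at the proximal end of the assembled sequence on the 4 large autosomal arms. The proximal 1 Mb was covered over 80.8% ± 3.03 on 2R, 72.5% ± 6.28 on 3L, 66.1% ± 5.41 on 2L and 40.2% ± 1.09 on 3R (SD, n = 2). The rest of these arms was covered over 15.8% ± 0.381, 11.1% ± 0.0910, 8.31% ± 0.145 and 7.10% ± 0.526 in the same order. On X the proximal 1 Mb was covered over 16.1% ± 2.07 and the rest over 7.58% ± 0.669.

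The ratio of proximal to remaining coverage was 7.96 ± 0.790 on 2L, 6.52 ± 0.617 on 3L, 5.69 ± 0.576 on 3R and 5.12 ± 0.315 on 2R (SD, n = 2). Circular shifts gave adjusted p-values of 0.004995 in both replicates for 2L and 3R (permutation test). For 3L they were 0.01499 and 0.03247, and for 2R 0.04995 and 0.03247, the first of these at the edge of the threshold. X, with a ratio of 2.15 ± 0.463, did not pass (permutation test, adjusted p 0.08791 and 0.1718). Its ratio was 1.04 with a 500 kb window. Whether X differs from the autosomal arms was not tested. In the combined list the ratios were lower, at 4.60 on 2L, 4.04 on 3L, 3.66 on 3R and 3.29 on 2R, and in the higher-scoring 50% of each replicate list they were higher, at 16.9, 11.3, 10.3 and 8.56. The call on 2R was lost with a 500 kb window, where the ratio was 4.63 and the larger adjusted p of the replicates 0.05744 (permutation test). Dense coverage of 2R ran past that window. It was 80.4% ± 2.07 from 0 to 0.5 Mb, 81.15% ± 3.99 from 0.5 to 1 Mb and 82.6% ± 2.70 from 1 to 1.5 Mb. Shifts that bring such sequence into the window raise p, so the lost call does not mean low proximal coverage. Assembled arms reach into pericentric sequence by different lengths in this release, so equal windows need not hold equal amounts of heterochromatin.

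Pooled over the 5 arms, coverage was highest within 1 Mb of the proximal end and lowest beyond 5 Mb. It was 55.1% ± 3.58 within 1 Mb, 33.5% ± 2.15 from 1 to 2 Mb, 23.2% ± 0.768 from 2 to 3 Mb, 23.4% ± 0.0834 from 3 to 4 Mb, 16.3% ± 0.193 from 4 to 5 Mb and 6.75% ± 0.591 beyond (SD, n = 2). On 2L it was 21.1% ± 2.70 from 1 to 2 Mb and 27.6% ± 1.47 from 3 to 4 Mb, and on X 4.47% ± 0.132 and 14.5% ± 0.839. The belt from 1 to 5 Mb, examined after the data were seen, was covered over 40.7% ± 0.849 on 2R, 31.1% ± 1.45 on 3L, 21.2% ± 1.74 on 2L and 16.9% ± 0.262 on 3R. These values were 4.25-, 4.43-, 3.91- and 3.18-fold those of the arm beyond 5 Mb, and the 4 arms passed in both replicates, the largest adjusted p being 0.04371 (permutation test). On X the belt had 1.53-fold the coverage of the sequence beyond and did not pass (permutation test, adjusted p 0.2328 and 0.2348).

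**Figure D2:**
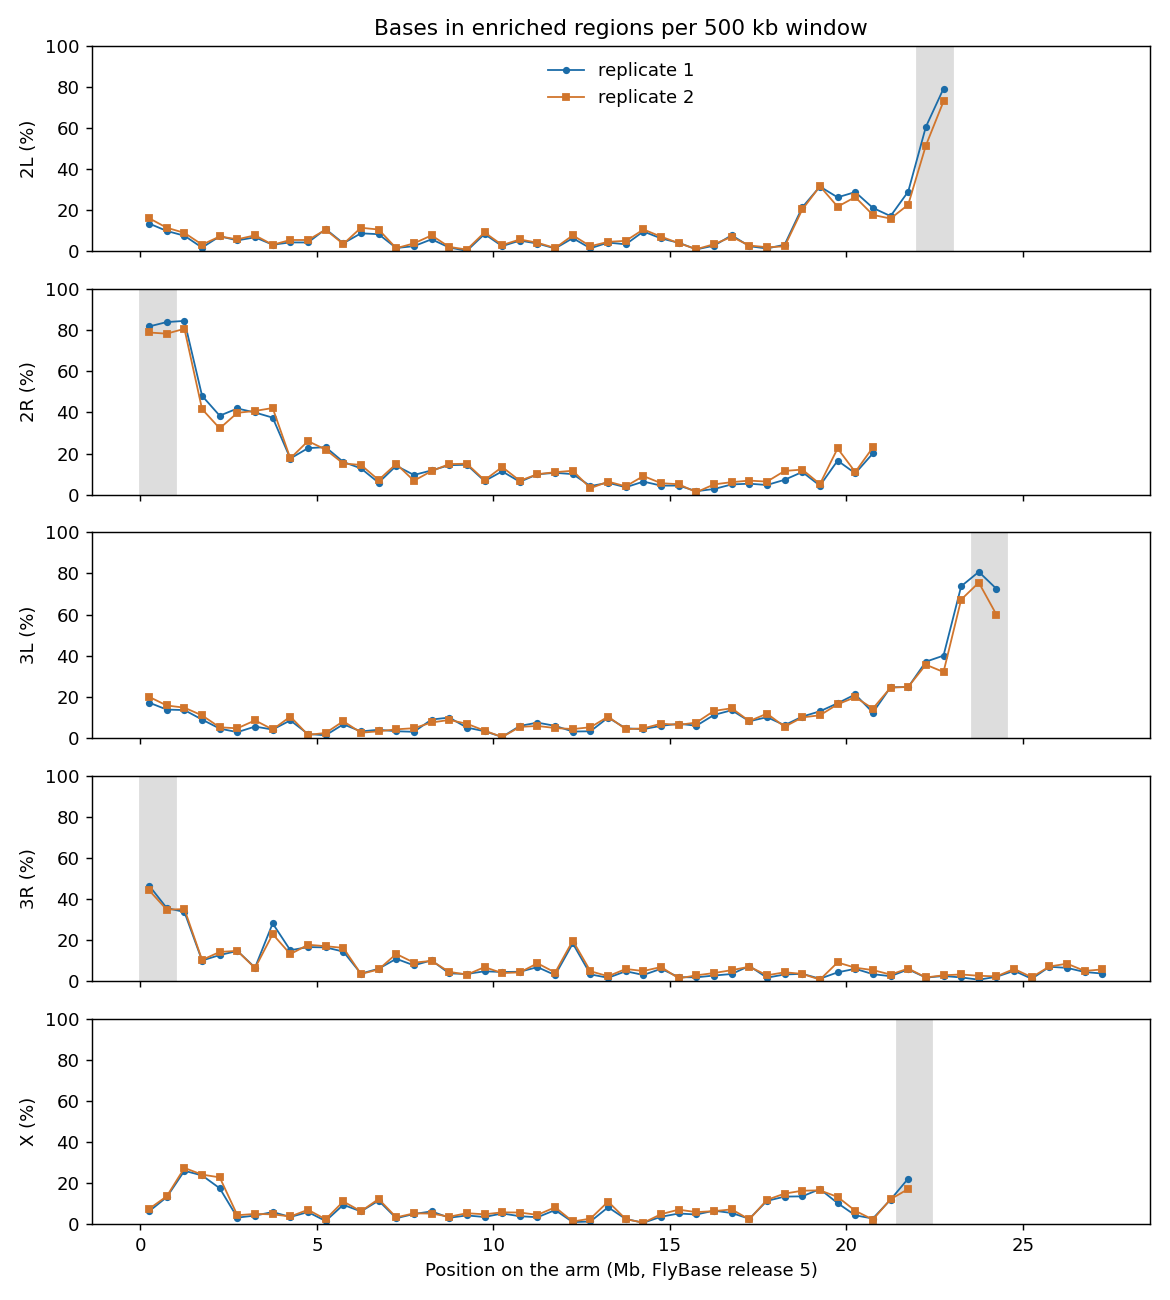
Percent of bases in enriched regions per 500 kb window (vertical axis) against position in Mb (horizontal axis) on 2L, 2R, 3L, 3R and X in replicate 1 (circles) and replicate 2 (squares); grey marks the proximal 1 Mb. Coverage is highest near the proximal end of 2L, 2R, 3L and 3R, while X has its highest window at 1 to 1.5 Mb (26.7%), towards the other end of the arm.

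The 5 widest regions held by both replicates lay in Het sequence or near the proximal ends of 2R and 2L. The widest was 3LHet 342797 to 434649 (91853 bp, combined score 1.08). The next were 2R 1433353 to 1510548 (77196 bp, score 1.56), 2L 22578857 to 22647369 (68513 bp, score 1.24), 2RHet 394466 to 456981 (62516 bp, score 1.48) and 2R 815379 to 876266 (60888 bp, score 1.18). By score, the 10 highest regions lay elsewhere, all on unplaced U, with scores of 3.15 to 4.13 and widths of 2470 to 3669 bp. The top region was U 7843121 to 7846421, with a score of 3.98 in replicate 1, 4.44 in replicate 2 and 4.13 in the combined list. It was followed by U 9526595 to 9529574 (combined score 3.64) and U 9552102 to 9555085 (3.57).

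Of the 10 highest-scoring regions on the euchromatic arms outside the proximal 1 Mb, 6 lay on 2R, 3 on 3L and 1 on 2L. The first 3 were 2R 1138777 to 1147657 (combined score 2.49), 2R 1216516 to 1229267 (2.44) and 2R 1258452 to 1267327 (2.04). On 3L they were 23506138 to 23509570 (1.86), 23334745 to 23348800 (1.83) and 23287544 to 23312129 (1.80). The region 2L 4948509 to 4951603 was the only one of the 10 that lay more than 5 Mb from a proximal end, with a score of 1.87 in replicate 1, 2.20 in replicate 2 and 2.00 in the combined list. The regions on 2R and 3L lay just outside the proximal 1 Mb, in densely covered sequence. Coverage was 82.6% ± 2.70 on 2R from 1 to 1.5 Mb and 70.5% ± 4.58 on 3L from 23 to 23.5 Mb (SD, n = 2). Their place on a euchromatic arm therefore does not show that they lie in euchromatin. Genes at these positions are not named, because the gene table at hand is of another release.

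The third question was whether regions in heterochromatin also had higher scores. The median score of regions on the Het sequences and chromosome 4 was 0.982 in replicate 1 and 0.955 in replicate 2. On the euchromatic arms it was 0.568 and 0.677. The difference was 0.414 in replicate 1 and 0.278 in replicate 2, and each exceeded all label permutations (p 1e-05, the smallest 100000 permutations can give). Het sequences alone, a setting added after the data were seen, exceeded the euchromatic arms by 0.447 in replicate 1 and 0.297 in replicate 2 (permutation p 1e-05 in each). Chromosome 4 therefore did not add to the pooled difference. Its 119 and 112 regions had median scores of 0.628 and 0.698, which exceeded those of the euchromatic arms by 0.0599 in replicate 1 (permutation p 0.00345) and by 0.0206 in replicate 2 (permutation p 0.3125). Set against the Het sequences, a comparison chosen after the data were seen, the median on chromosome 4 was lower in both replicates, with differences of -0.387 and -0.276 (permutation p 1e-05 in each). Within the euchromatic arms of replicate 1, the median score was 0.936 in the proximal 1 Mb, 0.652 from 1 to 2 Mb and 0.542 beyond 5 Mb. The corresponding values of replicate 2 were 0.994, 0.743 and 0.650. The regions are not independent, so these p-values are too small by an unknown amount.

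The fourth comparison was between the replicates. Most regions were found in both: 4620 of 6098 replicate 1 regions (75.8%, 95% interval 74.7 to 76.8) overlapped replicate 2, and 5005 of 6295 replicate 2 regions (79.5%, 78.5 to 80.5) overlapped replicate 1. Circular shifts gave 29.3% and 30.2% on average, at most 35.3% and 36.3%. The Jaccard index of covered bases was 0.659, against 0.124 on average and at most 0.172 in the shifts (one-sided permutation test, p 0.000999 for each of the 3 measures, the smallest 1000 shifts can give). The index by arm is to be read beside shifts within that arm, added after the data were seen, because chance overlap rises with coverage. It was 0.794 on 3LHet, against 0.448 on average in the shifts, although the share of replicate 1 regions with a partner there, 80.0%, did not exceed the 81.3% of the shifts. The index was 0.758 on chromosome 4 against 0.168, and 0.521 on X against 0.0413.

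The replicates differed in a directed way on pericentric sequence and on unplaced U. Of the replicate 2 regions on Het sequences 98.4% (97.3 to 99.0) had a partner in replicate 1, whereas 75.2% (72.3 to 77.8) of the replicate 1 regions there had a partner in replicate 2. Shifts within the Het sequences gave 75.7% and 66.6% on average. The shares in the same order were 91.4% (88.4 to 93.6) and 62.1% (58.1 to 65.9) on U, against 32.6% and 24.7% in the shifts. On chromosome 4 they were 91.1% (84.3 to 95.1) and 80.7% (72.7 to 86.8), against 49.3% and 45.7% in the shifts. The 2 intervals on chromosome 4 overlap, and the difference there was not tested. On the euchromatic arms the shares were 74.5% (73.2 to 75.7) and 77.6% (76.3 to 78.8), against 20.7% and 21.7% in the shifts. Replicate 1 covered 5.15 Mb of Het sequence and replicate 2 covered 3.99 Mb, while on the euchromatic arms they covered 13.8 Mb and 14.1 Mb.

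Higher-scoring regions were shared more often. In replicate 1 the shared percent was 60.3% in the lowest score quintile, then 67.8%, 78.7%, 86.2% and, in the highest, 85.8%. In replicate 2 it was 62.6%, 68.6%, 78.2%, 92.2% and 96.0%. On the euchromatic arms alone the top quintile of replicate 1 was shared at 95.9%. No shifts were run by quintile. Scores were higher on Het sequences, where shifts gave 66.6% of replicate 1 and 75.7% of replicate 2 regions. On the euchromatic arms shifts gave 21.7% and 20.7%, so part of the rise may come with location, which was not separated. Scores of 4620 overlapping pairs were correlated with a Spearman rho of 0.811 across regions, which are not independent replicates.

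**Figure D3:**
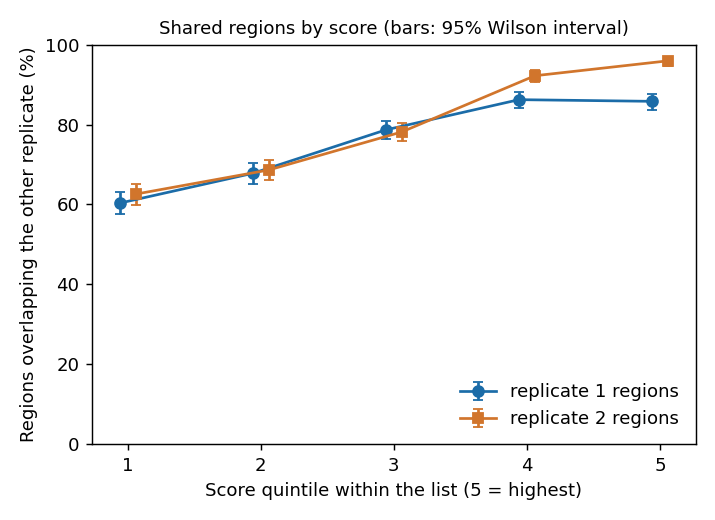
Percent of regions that overlap the other replicate (vertical axis) by score quintile within the list, 5 being the highest (horizontal axis), for replicate 1 (circles) and replicate 2 (squares); bars are 95% Wilson intervals. The percent goes from 60.3% to 85.8% in replicate 1 and from 62.6% to 96.0% in replicate 2.

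The last comparison was between the combined list and its replicates. It held 99.5% of replicate 1 regions and 99.2% of replicate 2 regions, with 29 and 50 missing. Of its 10603 regions, 4098 (38.7%, 95% interval 37.7 to 39.6) overlapped both replicates, 1282 (12.1%) replicate 1 alone, 1119 (10.6%) replicate 2 alone and 4104 (38.7%, 37.8 to 39.6) neither. The regions in both replicates made up 67.0% of the covered bases and those in neither 17.7%. Median widths were 3770 bp for regions in both and 1316 bp for regions in neither, and median scores were 0.618 and 0.381. Regions found in replicate 1 alone had a median score of 0.401 and those in replicate 2 alone 0.375, close to that of regions in neither. Regions in neither replicate made up 17.4% (15.2 to 19.9) on Het sequences, 23.9% (17.8 to 31.2) on chromosome 4 and 41.6% (40.5 to 42.6) on the euchromatic arms. With the replicate lists shifted together along each arm, added after the data were seen, these shares were 23.8%, 48.1% and 76.0% on average, and whether the classes differ beyond this was not tested. The overlap criterion changed these shares: with 50% reciprocal overlap, 28.9% of combined regions matched both replicates and 43.5% matched neither.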

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

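The settings with 200 kb blocks, Uextra, the regions past a sequence end, Het sequences alone and the 1 to 5 Mb belt were chosen only after the results were seen; the other settings were planned. Of the values under alternative settings, 143 counted as unchanged, 11 moved, 6 lost their call and 6 gained one. The 143 is not a measure of robustness. A call required both replicates, so one that passed could not be lost with either replicate alone. The setting without regions past a sequence end removed 1 of 6098 regions from replicate 1 and 0 from replicate 2, so it could change little. Unchanged values with a test kept their side of the threshold. Unchanged shares without a test stayed inside the interval for counting error of the main value. The 11 that moved were shares without a test and rho values. Direction was not kept in every unchanged value. The ratio of U, counted as unchanged, was 1.107 in the main setting and 0.935 with replicate 2 alone. Replicate overlap passed under every alternative run, from 62.8% to 79.1% of replicate 2 regions and 64.8% to 77.6% of replicate 1 regions. With 50% reciprocal overlap, combined regions in both replicates made up 28.9% and those in neither 43.5%, the shared top quintile was 75.5% in replicate 1 and 76.9% in replicate 2, and rho was 0.847; a stricter criterion matches fewer regions by construction. On the euchromatic arms alone, the top quintile of replicate 1 was 95.9% and rho 0.748. With a single replicate, combined regions overlapping it made up 49.2% to 50.7% and those not overlapping it 49.3% to 50.8%, because only 1 list has to match. The 200 kb blocks ended the calls on 2R (ratio 1.29, larger adjusted p of the replicates 0.08905), chromosome 4 (1.96, 0.1331) and 2LHet (2.85, 0.1934). They keep neighbouring regions together, and they leave few blocks on chromosome 4 (1.35 Mb) and 2LHet (0.369 Mb). Which of these ended the calls was not tested. Uextra lengthens the sequence without adding regions: it ended the call on 2L (0.890, adjusted p 0.08858) and put 3L at 1.12 (0.04949), above 1 in place of below. 3L also gained a call in the higher-scoring 50% (0.832, adjusted p 0.01154), and XHet in counts of regions (2.27, 0.03306), and the cause was not tested. With each replicate alone, ratios were 0.903 to 0.955 on 3L, 0.377 to 0.630 on YHet and 0.935 to 1.28 on U, each passing in 1 replicate. A 500 kb window ended the proximal call on 2R (4.63, adjusted p 0.05744, permutation test), where dense coverage runs past that window and raises p. Chromosome 4 alone had a score difference of 0.0403 averaged over the replicates, which assumes 1 score scale (larger permutation p 0.3125), and the cause was not tested. No paired analysis was possible because the inputs, tied to their ChIP libraries by the labels, have no values of their own here and the lists come from no test across samples. The planned feature and gene-list settings were not run for want of release 5 gene positions. Unknown read depth limits every statement on absent regions.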

Other observations

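The tests of the distal ends, of scores against regions found in 1 replicate, of library depth and of repeats in the replicate difference, of positions outside the replicates' regions, and the windows and regions named in the next 2 paragraphs were chosen only after the results were seen; the tests of short gaps, of weaker and narrower combined regions and of random shifts along the arms were set before theirs.

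Beyond 5 Mb from the proximal ends, 186 windows of 500 kb had a median coverage of 5.53% (interquartile range 3.67 to 8.72). The highest were 3 adjacent windows near the distal end of X, covered over 26.7% ± 0.984 from 1 to 1.5 Mb, 24.0% ± 0.273 from 1.5 to 2 Mb and 20.2% ± 3.75 from 2 to 2.5 Mb (SD, n = 2), together with 2R 5 to 5.5 Mb at 22.5% ± 0.843 and 2R 20.5 to 21 Mb at 21.5% ± 2.07. The window 3R 12 to 12.5 Mb reached 19.0% ± 0.967. The lowest were 3L 10 to 10.5 Mb at 0.410% ± 0.0379 and 2L 9 to 9.5 Mb at 0.601% ± 0.420. The 5 highest-scoring regions in this part of the genome were 2L 4948509 to 4951603 (combined score 2.00), X 4533148 to 4538602 (1.71), 3R 12623272 to 12625641 (1.68), X 1843670 to 1849813 (1.64) and 3L 9436493 to 9440623 (1.58), each held by both replicates.

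Chromosome 4 was covered unevenly. Its 100 kb windows ranged from 4.71% ± 2.80 at 0.2 to 0.3 Mb to 55.1% ± 6.39 at 0.7 to 0.8 Mb (SD, n = 2). The first window had 40.0% ± 9.77 and the stretch from 0.1 to 0.2 Mb 9.47% ± 0.450. The single region listed as depleted in replicate 1 was 4 1073656 to 1075366 (score -0.0115). It lay wholly inside an enriched region of replicate 2, 1073477 to 1075517 (score 0.723, above 51.0% of replicate 2 regions), and of the combined list (score 0.375). The nearest enriched regions of replicate 1 were 18608 and 6226 bp away.

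Replicate 1 covered more pericentric sequence than replicate 2, 5.15 against 3.99 Mb, a ratio of 1.29 that lay above 1 on all 6 Het sequences; median scores there were 1.01 and 0.974. A lower calling limit or a deeper library in replicate 1 would be expected to add euchromatic sequence too, if the signal there were equal. The euchromatic ratio was 0.976 (13.8 against 14.1 Mb), made up of 1.096 in the proximal 1 Mb and 0.949 in the rest, beside 1.15 on chromosome 4. These values cannot decide on either cause, because weaker euchromatic signal in replicate 1 could offset the added sequence. Median scores on these arms were 0.568 in replicate 1 and 0.677 in replicate 2, but whether the lists share a score scale is unknown. Short gaps in replicate 2 are argued against, since the pericentric ratio stayed at 1.29 after gaps of up to 1 kb were closed. A different treatment of repeat-rich sequence in the libraries or their inputs may be involved: unplaced U had a ratio of 1.47, but a difference in the chromatin of the samples would raise it too, so these cannot be told apart. Both libraries belong to 1 group, so no biological explanation was tested.

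The combined list had 4104 regions found in neither replicate. They may be weaker sites that pass only when the replicates are combined, but the scores leave this open: such a region scored below one found in both replicates in 82.8% of pairs, below one found in replicate 1 alone in 54.8% and below one found in replicate 2 alone in 46.2%. A smaller minimum width in the combined list would not account for all of them if a site has the same width in each list, which was not tested. Of these regions 48.3% were narrower than the narrowest replicate region (1301 bp), and their median width of 1316 bp was close to that limit. Random placement was first tested by shifting them to any position, which gave a ratio of 1.03 between the replicate 1 coverage of the surrounding 100 kb and that of the shifts (14.7% against 14.3%, permutation p 0.2318), the value set beforehand for random placement; this was then set aside because shifted regions could land on replicate regions, where these by definition cannot lie. A second test, chosen after that result and limited to positions outside the replicates' regions, gave 1.52 (14.7% against 9.65%, at most 10.9% in 1000 shifts, permutation p 0.000999), which argues against random placement and is weaker evidence for having been chosen late.

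Coverage might rise towards the distal ends, as binding near telomeres would predict, and the data leave this open. Coverage of the distal 1 Mb was higher than in the remaining arm beyond 5 Mb from the proximal end in both replicates on 4 of 5 arms. It was 12.8% ± 1.47 against 5.03% ± 0.511 on 2L, 16.6% ± 1.70 against 6.52% ± 0.338 on 3L, 15.4% ± 1.42 against 9.24% ± 0.637 on 2R and 10.2% ± 0.562 against 6.70% ± 0.645 on X (SD, n = 2), while 3R had 5.44% ± 1.22 against 5.38% ± 0.638. In circular shifts 0 of 5 arms passed in both replicates after adjustment over 5 arms and 2 of 5, 2L and 3L, did so without it (permutation test, adjusted p 0.06244 and 0.03746 for each). A p-value above the threshold does not exclude a rise on the 4 arms, and finer distances from the telomere were not tested.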
